A study of Mus musculus with 3 samples.

How the data were processed

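The series holds 3 MoGene-2_0-st arrays of mouse liver, 1 each for no treatment, TMA and EEC+TMA, per the labels. Total RNA was purified from 100 mg of frozen liver with a phenol-type reagent, made into sense cDNA, fragmented and labelled with biotin, per the labels' protocols. The mice were 8 weeks old at the start and 10 weeks old at sampling. The extract was given by mouth for 2 weeks and TMA was applied for 24 hours, per the labels' protocols. The sex of the mice, the dose and route of TMA, the dose of the extract, and whether RNA was pooled are not given in the sources used here.

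The authors deposited 1 log2 value per probe set and array. A table that the authors named raw data holds the same log2 values rounded to 5 decimals, with a largest difference of 5e-05. The summary and normalization method is not given in the sources used here. The quartiles of the 3 arrays lay close together (medians 3.16, 3.16 and 3.08), so the deposited log2 values were taken as normalized between arrays. Of the 33793 main probe sets 18021 had exactly the same value on the untreated and TMA arrays, 18397 on the TMA and EEC+TMA arrays, 21256 on the untreated and EEC+TMA arrays, and 15716 on all 3, which puts the median difference between arrays at 0. The authors also deposited lists of probe sets with a signed fold between 2 arrays, which equals 2 to the power of the log2 difference, or minus its inverse where the first array is lower. The p-values and false discovery rates per KEGG map and GO term were deposited by the authors for these lists, with the tool not given in the sources used here. Deposited counts of genes per map and term were copied as given.

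Gene symbols, Entrez identifiers and coordinates were taken from the files, and 31873 of the main probe sets had a symbol. Of 25901 genes with an Entrez identifier 25453 were found in the reference gene table of assembly GRCm38.p6, and 24160 had the same symbol there. The genome build of the coordinates is not given in the sources used here, and 99.0% of the matched probe sets overlapped the locus of the reference table. The symbol was the unit of reporting. For the 657 symbols with several probe sets, the one with the highest mean over the arrays was used. The files mark 3715 genes' probe sets as matching more than their own transcript, and such genes are named as doing so.

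A probe set counted as measured on an array where its value reached the 95th percentile of the 1523 chemosensory receptor probe sets on that array. Genes counted as 2-fold apart when the log2 difference, with each array first raised to its background level, was at least 1 in size. A gene measured on 1 array alone was given as at least N-fold, against the background level of the other. No test was made, since 1 array per group leaves no spread. Each comparison names, with a few left out, the 12 genes with the largest difference each way among genes measured on both arrays, leaving out predicted and numbered loci, microRNA, small nucleolar RNA and chemosensory receptor symbols. It also names the 3 largest each way measured on 1 array, up to 4 members of each list, Fmo1, Fmo2, Fmo4 and Fmo5, Xist and the Y-linked genes. Where the text names other genes of a count, they were chosen after their values were seen.

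There were 32 pathway lists and 16 cell type lists, with 914 entries, of which 22 were missing from the arrays. The median log2 difference of each list's measured members was placed among 10000 random lists of the same size drawn from genes measured on both arrays, matched in 20 bins of mean level. A list below percentile 2.5 or above 97.5 lay outside the random range, and lists with fewer than 4 measured members were not placed. Neutrophil markers and gallbladder and intestine markers had too few. Percentiles describe these arrays and are not p-values. Because many genes have identical values, the random range was narrow or 0 wide in places, and small medians could then lie outside it. Control probe sets were placed among random sets of main probe sets in the same way.

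The groups, the size rule, the lists and the alternatives were fixed before the data were examined. Alternatives were median centring, quantile normalization over the 3 arrays, loess of the difference on mean level (span 0.3), other background levels, the mean of all probe sets of a symbol, thresholds of 1.5-fold and 3-fold, the second table of values, random lists not matched on level, and the mean of list members. Unique probe sets alone, and the count without 3812 small RNA genes and antigen receptor segments, were added after the data were seen. The 3 values of each gene were shuffled 1000 times in the deposited scaling, and, added later, after quantile normalization.

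The scripts were tested on simulated data built on TMA against no treatment, with 30921 genes for the folds, 15173 for the lists, and an error of 0.2 (SD, log2). Of 50 genes changed at each size, 6% were called at 1.5-fold, 82% at 2.5-fold, 100% at 4-fold and 100% at 8-fold, and 6 of 30721 unchanged genes were called. Of 500 random lists without a shift 5.6% lay outside the random range, and 99 of 100 lists shifted by 0.3 did. The simulated error was independent and equally large for every gene and left no identical values, unlike these arrays, and the changed genes all lay well above background. The simulated rates therefore check the scripts and are not error rates of these arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.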

Results

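Liver RNA from ICR mice, an outbred laboratory stock, was measured on 3 MoGene-2_0-st arrays, which carry probe sets for coding and non-coding mouse transcripts. The mice were 10 weeks old at sampling. There were 3 groups with 1 array each. The no treatment group was left untreated, the TMA group was given distilled water and then trimethylamine (TMA), and the EEC+TMA group was given an ethanol extract of the brown alga Ecklonia cava (EEC) and then TMA. Trimethylamine is a volatile amine with a fishy odour that the liver oxidises with flavin-containing monooxygenases, and the study's title concerns the deodorizing potential of the alga. With 1 array per group there was no replicate, no spread between animals and no test, so every difference below compares arrays, not conditions, and the number of arrays limits the precision. The labels do not say whether an array holds RNA from 1 animal or from several.

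The tables held log2 values of 41345 probe sets, of which 33793 belonged to the main design and stood for 30921 gene symbols. The background level, taken from 1523 probe sets of chemosensory receptor genes, was 3.14 on the untreated array, 3.25 on the TMA array and 3.15 on the EEC+TMA array. By that level 16319, 16039 and 16326 genes were measured, in the same order. Across genes measured on both arrays of a pair, 95% of the log2 differences lay between -0.81 and 0.55 for TMA minus no treatment, between -0.54 and 0.72 for EEC+TMA minus TMA, and between -0.67 and 0.41 for EEC+TMA minus no treatment. Of the 1523 chemosensory probe sets, which serve as a background measured in the same way, 13, 12 and 6 lay at least 2-fold apart in these pairs. Of all 30921 genes 307, 159 and 203 did under the size rule. The shares were thus of the same order, and 2-fold differences also arose among receptor genes that liver should not express.

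The TMA array differed from both others in its control probe sets. Poly-A spike-in probe sets, which read RNA added to the sample before labelling, were 1.99-fold higher on the TMA array than on the untreated array in the median of 39, with 38 of them higher. Against the TMA array they were 1.99-fold lower on the EEC+TMA array. Exon normalization controls went the other way, with a median of 6.07 on the TMA array, 6.43 on the untreated array and 6.49 on the EEC+TMA array. These values stand beside each comparison that uses the TMA array.

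**Figure D1:**
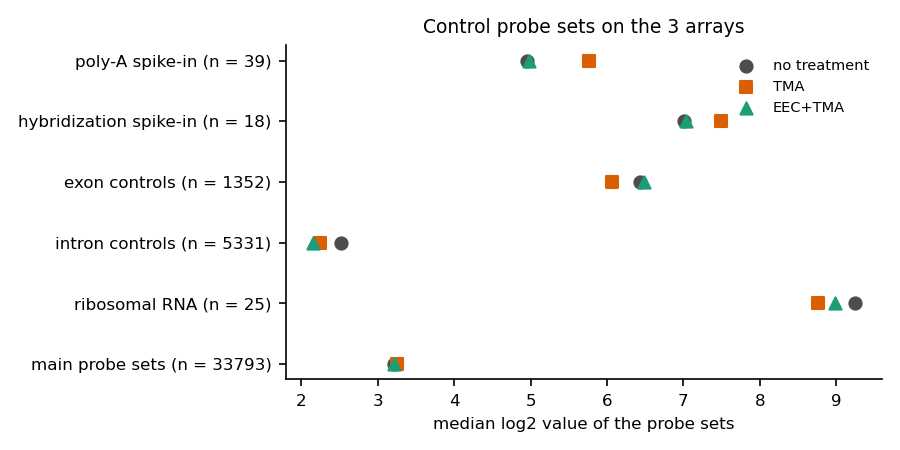
Median log2 value (horizontal axis) of 5 kinds of control probe set and of the main probe sets on the untreated, TMA and EEC+TMA arrays, with 1 point per array and n the number of probe sets. The poly-A spike-in median was 5.76 on the TMA array against 4.95 and 4.98 on the untreated and EEC+TMA arrays.

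The first comparison set TMA against no treatment, which addresses what trimethylamine does in the liver. The TMA group was also given distilled water for 2 weeks which the labels do not give for the no treatment group, so the comparison holds both differences. Genes of hepatic metabolism led the lower side. Igfbp1, which encodes a liver-secreted binding protein for insulin-like growth factors and is repressed by insulin (chromosome 11, 7197782 to 7202546), was 5.73-fold lower on the TMA array, at a log2 level of 5.03 against 7.55. Slc22a30, a member of the organic ion transporter family, was 4.84-fold lower, and the cytochrome P450 gene Cyp3a25 (chromosome 5, 145977194 to 146009618) 3.72-fold lower. On the higher side stood Cyp2b9, a cytochrome P450 gene with female-biased expression in mouse liver (chromosome 7, 26173409 to 26210661), 4.09-fold higher at 8.27 against 6.24, and the acute phase genes Orm2 (2.29-fold) and Saa2 (2.08-fold). The coordinates are those of the files, whose genome build is not given in the sources used here.

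Under the size rule 307 genes were at least 2-fold apart, 105 higher and 202 lower on the TMA array, so that 34.2% were higher. Quantile normalization turned the balance to 148 higher and 130 lower, and a loess correction for level gave 132 higher and 143 lower. Small RNA genes and antigen receptor segments made up most of the higher genes, and without them 23 were higher and 160 lower.

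Further genes among the 12 with the largest differences each way were the mitochondrial carrier genes Slc25a30 (3.13-fold lower) and Slc25a25 (2.84-fold lower), the odorant binding protein gene Obp2a (3.11-fold lower), the RNA helicase gene Ddx5 (3.03-fold lower), the stress gene Gadd45g (2.91-fold lower), the nuclear non-coding RNA Malat1 (2.88-fold lower), the male-biased P450 gene Cyp4a12b (2.86-fold lower, by a probe set that also matches other transcripts) and Onecut1, a hepatocyte transcription factor gene (2.85-fold lower). On the higher side were Mettl7a3 (3.20-fold), the T cell receptor segment Traj43 (3.11-fold), Fbxw23 (3.11-fold), the U3 small nucleolar RNA gene Rnu3a (3.04-fold), Rny1 (2.67-fold), Bcl2a1c (2.65-fold), the histone gene Hist1h4k (2.55-fold), Rab44 (2.25-fold), Scarna3a (2.23-fold) and Ep400 (2.13-fold). Rny1, Bcl2a1c, Hist1h4k and Scarna3a were read by probe sets that also match other transcripts. With all probe sets of a symbol averaged, the log2 difference was 0.25 for Ep400 and 0.66 for Rab44. Of genes above background on 1 array alone, Mup-ps16 was at least 4.15-fold lower and Zfp125 at least 2.18-fold lower on the TMA array, while Mnda was at least 1.85-fold, Tmem114 at least 1.77-fold and Sox2 at least 1.72-fold higher.

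**Figure D2:**
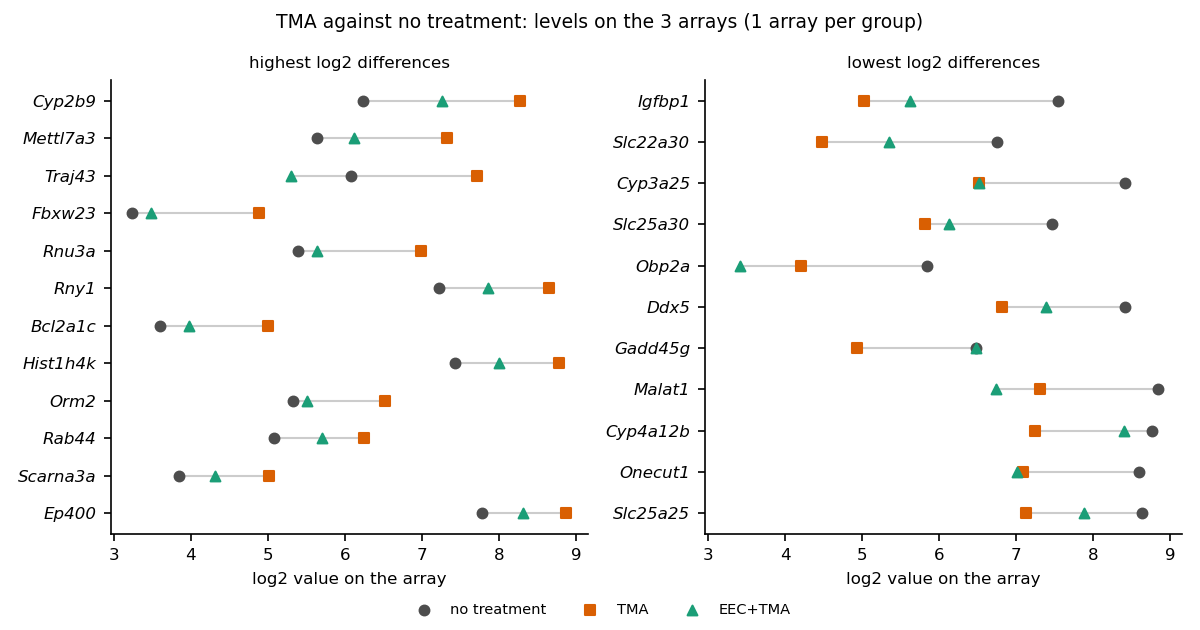
Log2 value (horizontal axis) on the untreated, TMA and EEC+TMA arrays of genes among the 12 with the highest and the 12 with the lowest log2 difference of TMA minus no treatment; each point is 1 array. Igfbp1 stood at 7.55 on the untreated array, 5.03 on the TMA array and 5.62 on the EEC+TMA array.

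Of the 46 gene lists with enough measured members, 6 had a median outside the central 95% of 10000 random lists matched on level. Lists of randomly drawn genes would give 2.3. Members of a list can vary together between any 2 arrays, so the number to be had without an effect of treatment is not known. The male-biased liver genes were lower together: 17 of 18 measured members lay below 0, with a median log2 difference of -0.58 at percentile 0, among them Cyp4a12b, Cyp2d9 (2.18-fold lower), Cyp4a12a (1.93-fold lower) and Nudt7 (1.85-fold lower). Their median was -0.36 with 16 of 18 lower under quantile normalization and -0.38 with 14 of 18 lower under loess. The female-biased list, which holds Cyp2b9, had a median of 0 over 15 members, with 3 higher, 7 lower and 5 identical. The 4 Y-linked genes, all measured, were lower with a median of -0.75 at percentile 0.100, and lay inside the random range at percentile 3.15 with no background level. Uty and Kdm5d were 2.42-fold and 2.26-fold lower, whereas Ddx3y and Eif2s3y were 1.26-fold and 1.06-fold lower, the latter turning higher under quantile normalization and loess. Xist, the X-inactivation transcript of female cells, read 1.57 on each array, below background.

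Bile acid genes had a median of -0.35 at percentile 2.38, with 19 of 25 members lower. The canalicular transporter genes Abcc2 and Abcb4 were each 2.14-fold lower (under 2-fold after quantile normalization and loess, as was Cyp2d9) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 1.82-fold lower. That list moved inside the random range in 5 alternatives, at percentile 9.96 under quantile normalization and 2.83 under loess, with 14 members lower and 11 higher under both. RNA splicing factors had a median of -0.25 at percentile 1.47, led by Ddx5 and Clk1 (1.54-fold lower), and lay inside the random range under quantile normalization (percentile 2.62) and by their mean. Kupffer cell and macrophage markers had a median of 0.08 at percentile 100, with 9 of 14 members higher, 2 identical and 3 lower. Marco was 1.43-fold, Cd5l 1.42-fold and C1qb 1.36-fold higher, while Folr2 was 1.21-fold lower and Clec4f identical. The 5 measured B and plasma cell markers were all higher, with a median of 0.29 at percentile 99.7, including Ighg2c (1.45-fold) and Cd74 (1.25-fold). On the untreated array Cd79a (3.26) and Ighg2c (3.32) lay near the background of 3.14, while Cd74 (6.29) and Ighm (7.08) lay well above it. Antigenomic background probe sets, which read signal without a target, were also higher on the TMA array, by a median of 0.82 among the 11 measured on both. The poly-A spike-in difference of 0.99 (log2) lies beside these lists too.

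Other lists held single genes with large differences while their medians stayed inside the random range. Acute phase proteins had a median of -0.06 at percentile 95.1 with 9 of 22 members higher, and that median turned to 0.14, at percentile 99.2, under loess and to 0.04 under quantile normalization. Among them Lbp was 1.88-fold and Hamp 1.74-fold lower beside the higher Orm2 and Saa2. In the gluconeogenesis and fasting list, at percentile 29.4, the glucose-6-phosphatase gene G6pc was 2.49-fold and the insulin receptor substrate gene Irs2 2.45-fold lower. Xenobiotic P450 genes, at percentile 39.3, held both Cyp2b9 and Cyp3a25, which differed in opposite directions. Among conjugating enzymes Ugt2b5 was 2.54-fold lower. Of the genes that oxidise trimethylamine, Fmo1 and Fmo5 were 1.35-fold and 1.36-fold lower, Fmo2 1.08-fold lower, and Fmo4 identical on both arrays. NRF2 antioxidant targets, at percentile 88.1, had no member 2-fold apart.

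The second comparison set EEC+TMA against TMA, which asks what the extract adds in mice exposed to trimethylamine. The fatty acid hydroxylase genes Cyp4a32 (chromosome 4, 115600938 to 115622366), Cyp4a10 and Cyp4a14, targets of the lipid-sensing receptor PPARalpha, were 3.11-fold, 2.82-fold and 2.12-fold higher on the EEC+TMA array. Of single acute phase genes, Saa2 (chromosome 7, 46751833 to 46754314) was 3.09-fold, Orm2 2.02-fold and Saa1 1.65-fold lower. Cyp2b9 was 2.03-fold lower on the EEC+TMA array, at 7.26. Ifitm2, an interferon-induced membrane protein gene (chromosome 7, 140954837 to 140955983), was 3.76-fold and the carboxylesterase gene Ces2c 3.47-fold higher.

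In all, 159 genes were at least 2-fold apart, 99 higher and 60 lower on the EEC+TMA array, or 62.3% higher. Quantile normalization gave 60 higher and 91 lower, and loess 63 higher and 83 lower, so the balance depended on the scaling. Without small RNA genes and antigen receptor segments 78 were higher and 21 lower.

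The other leading genes on the higher side were the kinase gene Map3k13 (3.25-fold), the male-biased monooxygenase gene Moxd1 (3.23-fold), Eif4ebp3, a repressor of translation initiation (2.94-fold), Gadd45g (2.91-fold), the transcriptional repressor gene Bcl6 (2.75-fold) and the mitochondrial transfer RNA genes mt-Ts2 (2.74-fold) and mt-Tt (2.66-fold). On the lower side were Traj43 (5.34-fold), Abcd2, a peroxisomal transporter of very long chain fatty acids (3.31-fold), Fbxw23 (2.64-fold), Tmed2 (2.58-fold), Rnu3a (2.54-fold), Mettl7a3 (2.31-fold), Zfp946 (2.20-fold), Fgl1, a protein secreted by hepatocytes (2.16-fold), Igkj3 (2.15-fold), Hook3 (2.13-fold) and Igkv4-86 (2.08-fold). Cyp4a10, Igkj3 and Igkv4-86 were read by probe sets that also match other transcripts. Of genes above background on 1 array alone, Mup-ps16 was at least 2.86-fold, Ifit3 at least 1.85-fold and Ces2b at least 1.84-fold higher, and Smok4a at least 1.88-fold, Tet2 at least 1.83-fold and Igkv5-37 at least 1.63-fold lower.

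**Figure D3:**
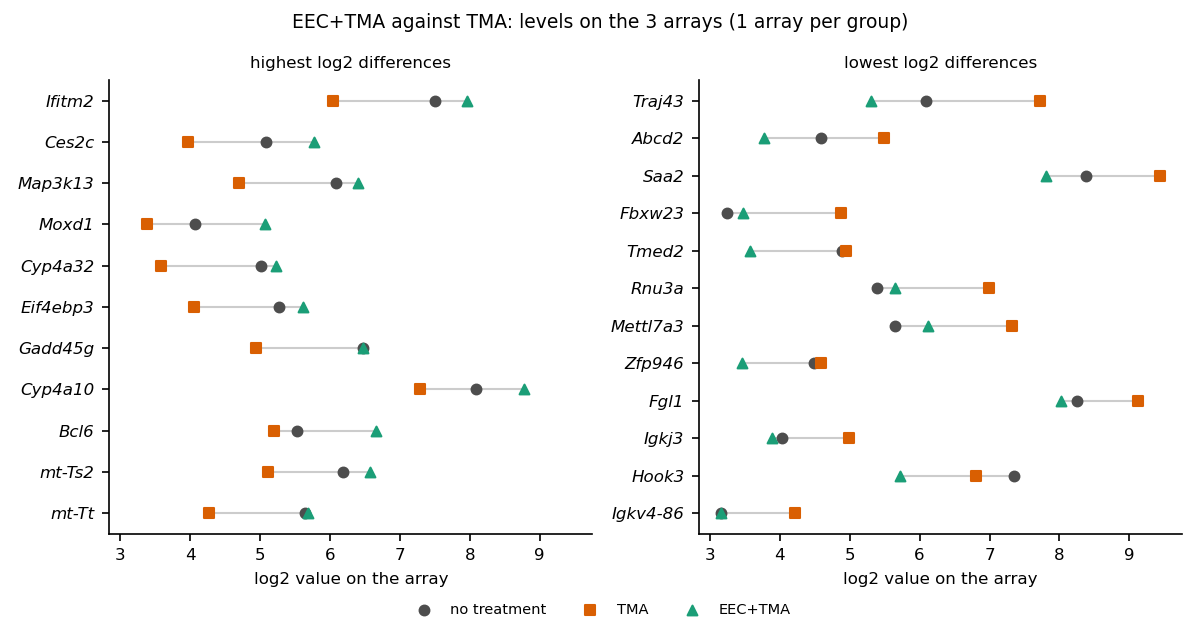
Log2 value (horizontal axis) on the untreated, TMA and EEC+TMA arrays of genes among the 12 with the highest and the 12 with the lowest log2 difference of EEC+TMA minus TMA; each point is 1 array. Saa2 stood at 8.38 on the untreated array, 9.44 on the TMA array and 7.81 on the EEC+TMA array.

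Among the lists, 6 of 46 lay outside the random range. The male-biased genes were higher together, with 15 of 18 members above 0 and a median of 0.59 at percentile 100, among them Moxd1, Cyp2d9 (2.62-fold), Cyp4a12b (2.22-fold) and Selenbp2 (1.91-fold). The TMA array also gave the median of -0.58 of this list against no treatment, so the 2 shifts are not independent results. Gluconeogenesis and fasting genes had a median of 0.38 at percentile 99.5 with 17 of 18 higher, none of them 2-fold. Trib1 was 1.76-fold, Lpin1 1.58-fold, Igfbp1 1.51-fold and Pck1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, 1.44-fold higher. Both lists stayed outside the random range under quantile normalization and loess, with smaller medians: 0.20 (12 of 18) and 0.18 (11 of 18) for gluconeogenesis and fasting, and 0.35 (15 of 18) and 0.36 (14 of 18) for the male-biased genes.

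Fatty acid oxidation genes had a median of 0.29 at percentile 98.1, with 25 of 29 members higher. The list for FMO monooxygenases and trimethylamine handling had a median of 0.35 at percentile 98.4, with 13 of 15 members higher. Within it the carnitine transporter gene Slc22a5 was 1.80-fold, Pemt 1.55-fold, Fmo1 1.43-fold, Dmgdh 1.43-fold and Fmo5 1.33-fold higher, while Fmo2 was 1.14-fold lower and Fmo4 identical on both arrays. Neither list stayed outside under another scaling: fatty acid oxidation lay at percentile 96.9 under quantile normalization and 91.3 under loess, and also inside with no background level, and the FMO list at 96.1 and 97.1. Each of these lists moved beside spike-in controls that differed by -0.99 (log2).

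B and plasma cell markers had a median of -0.18 at percentile 1.01 over 5 members, with Ighg2c 1.45-fold lower and Cd74 1.85-fold higher, and lay inside the random range at percentile 5.34 under quantile normalization and in 3 other alternatives. The Y-linked genes had a median of -0.36 at percentile 0.120, with 3 of 4 lower and Kdm5d 1.65-fold higher, and their mean lay inside the random range at percentile 3.48. Acute phase proteins as a list lay at percentile 29.5, with 16 of 22 members higher, among them Saa3 (1.86-fold), and its median of 0.15 turned to -0.04 under loess. Other lists held single genes at least 2-fold apart: the glutathione transferase genes Gstm3 (2.20-fold higher) and Gstt2 (2.04-fold higher), the bile transporter gene Abcb4 (2.29-fold higher) and the interferon-induced gene Igtp (2.16-fold higher). Gstm3, Gstt2 and Abcb4, like Cyp4a14 and Cyp4a12b, fell short of 2-fold under quantile normalization and loess, and Igtp under quantile normalization.

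**Figure D4:**
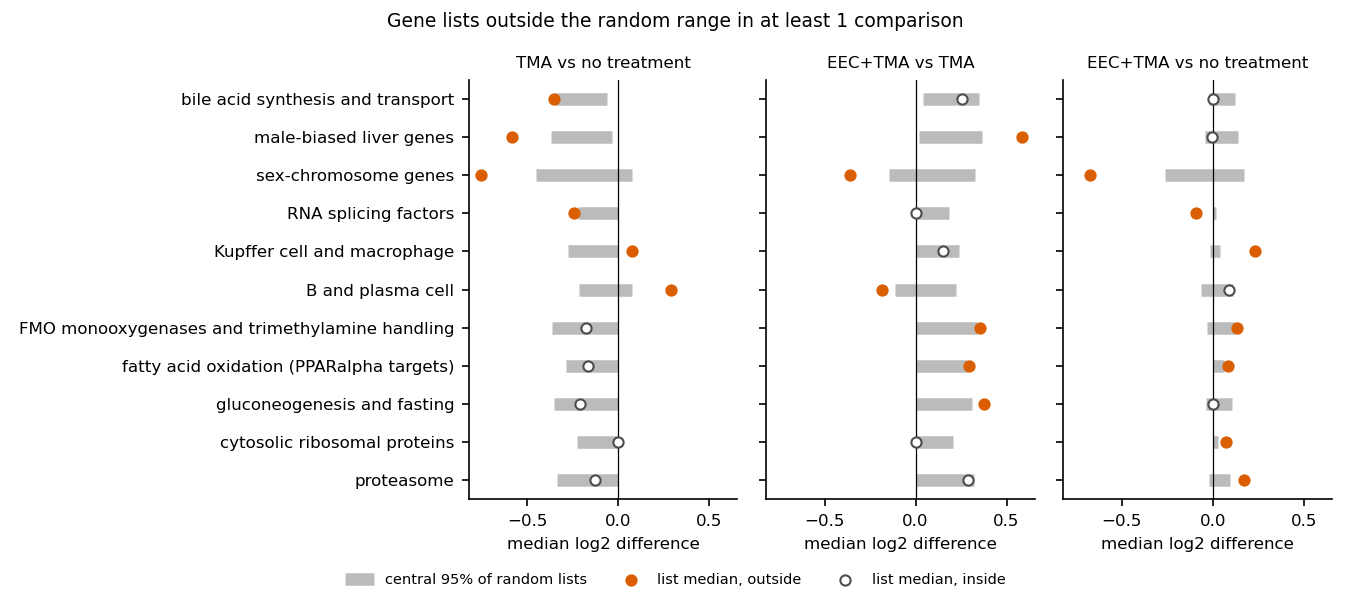
Median log2 difference (horizontal axis) of the lists that lay outside the random range in at least 1 comparison, 1 panel per comparison. Grey bars span the central 95% of 10000 random lists matched on level, filled points lie outside and open points inside; the male-biased list stood at -0.58, 0.59 and -0.00325.

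The third comparison set EEC+TMA against no treatment. Among the highest genes, Apol9a (chromosome 15, 77403789 to 77411080) was 3.21-fold, H2-Ab1, a class II histocompatibility gene, 2.48-fold, Cd74, the class II invariant chain (chromosome 18, 60803848 to 60812652), 2.31-fold, the interferon-induced GTPase gene Igtp 2.16-fold and the chemokine gene Cxcl9 2.03-fold higher on the EEC+TMA array. On the lower side were Obp2a (5.37-fold), Malat1 (4.28-fold; chromosome 19, 5795690 to 5802671), Igfbp1 (3.80-fold) and Cyp3a25 (3.71-fold). Cyp2b9 was 2.02-fold higher.

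There were 203 genes at least 2-fold apart, 27 higher and 176 lower on the EEC+TMA array, or 13.3% higher. Quantile normalization gave 27 higher and 162 lower, and loess 27 higher and 178 lower. The remaining genes of the lower side were Arhgap5 (3.71-fold), the ubiquitin peptidase gene Usp34 (3.54-fold), Nbeal1 (3.52-fold), Zbed6 (3.36-fold), the ion channel gene Trpm7 (3.33-fold), Uty (3.31-fold), Dmxl1 (3.24-fold) and Vps37a (3.22-fold). On the higher side were also Apol9b (higher by 1.32 in log2) and Gbp10 (2.37-fold), both read by probe sets that match other transcripts too. Bcl6 (2.19-fold), Slc41a2 (2.17-fold) and Esd (2.06-fold) were higher as well. Moxd1, with a log2 difference of 0.9995, fell just short of 2-fold. Of genes above background on 1 array alone, Tet2 was at least 4.40-fold, Zfp960 at least 2.71-fold and Zfp125 at least 2.35-fold lower, and Ifit3 at least 2.00-fold, Galr3 at least 1.70-fold and Cdkn2c at least 1.60-fold higher.

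In this comparison 7 of 46 lists lay outside the random range, and each kept its side under quantile normalization and loess. Kupffer cell and macrophage markers had a median of 0.23 at percentile 100, with 12 of 14 higher, including C1qb (1.73-fold), Cd5l (1.60-fold), Csf1r (1.33-fold) and Clec4f (1.30-fold). Proteasome genes had a median of 0.17 at percentile 99.9 with 20 of 22 higher, and Psmb6 was 1.34-fold higher. Cytosolic ribosomal protein genes had a median of 0.07 at percentile 99.5, fatty acid oxidation genes 0.08 at percentile 99.0 and the FMO list 0.13 at percentile 98.0; none of their members was 2-fold apart. RNA splicing factors had a median of -0.09 at percentile 0.05, with Ddx5 2.03-fold (under 2-fold after quantile normalization), Clk1 1.65-fold and Srsf5 1.48-fold lower. All 4 Y-linked genes were lower, with a median of -0.67 at percentile 0.0700.

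Male-biased genes showed no common shift here, with a median of -0.00325 at percentile 10.3. The core clock gene Clock was 2.78-fold lower, while its list stayed at percentile 48.6. Interferon-stimulated genes had a median of 0 over 20 members, a value that decides nothing because the random range was 0 wide. Their mean of 0.16 lay at percentile 99.9, and Irf9 was 1.76-fold higher.

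The 2 steps were also set side by side: TMA minus no treatment, then EEC+TMA minus TMA. Ifitm2, Ces2c, Cyp4a32, Gadd45g, Map3k13, Abcb4, Cyp2d9 and Cyp4a12b were among 40 genes at least 2-fold lower on the TMA array than on the untreated array and at least 2-fold higher again on the EEC+TMA array. Abcb4, Cyp2d9 and Cyp4a12b missed 2-fold in at least 1 step under quantile normalization and loess. Cyp2b9, Saa2, Orm2, Traj43 and Mettl7a3 were among 37 genes with the reverse order. Across 15654 genes measured on all 3 arrays, the correlation of the steps was -0.65 (Spearman -0.67), a value across genes, which are not independent replicates. The TMA array enters both steps with opposite sign, and equal independent error on each array gave a simulated correlation of -0.50. The spread was not equal: the variance particular to each array was 0.0594 for TMA, 0.0449 for no treatment and 0.0204 for EEC+TMA, and these variances, computed from the same differences, give the observed correlation by construction. With the 3 values shuffled within each gene 1000 times, the mean count was 21.3 (central 95% from 15.0 to 29) for lower then higher and 45.0 (35 to 56) for higher then lower; the total of 77 lay inside its range of 54.0 to 79. After quantile normalization the counts were 26 (shuffled 12 to 25) and 58 (33 to 54), and the total of 84 lay above its range of 50 to 74.0. The covariance was -0.0594, against -0.0432 after shuffling, and independent lists of these sizes would share 0.647 and 0.204 genes. How much of the opposite order comes from the shared array was not separated.

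**Figure D5:**
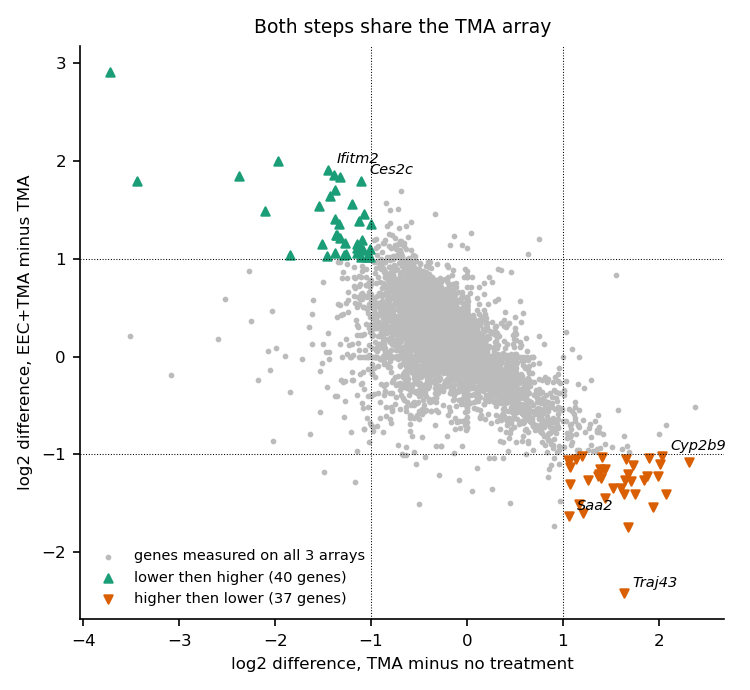
Log2 difference of EEC+TMA minus TMA (vertical axis) against TMA minus no treatment (horizontal axis), 1 point per gene measured on all 3 arrays, with dotted lines at 2-fold. Coloured triangles mark the 40 genes lower then higher and the 37 genes higher then lower, drawn at their deposited values.

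The authors' deposited tables list probe sets rather than genes. The authors' deposited table for TMA against no treatment held 198 probe sets, 71 higher and 127 lower, and that for EEC+TMA against TMA held 68, of which 35 were higher and 33 lower. Both were recovered in full as the main probe sets at least 2.5-fold apart in the deposited log2 values. In the authors' deposited table for the first comparison 94 of the 198 probe sets were small RNA genes or antigen receptor segments, 26 had no symbol and 17 lay below background on both arrays. In the authors' deposited table for the second these numbers were 34, 7 and 5. The 2 lists shared 38 probe sets, and 37 of these had opposite directions. Because the TMA array enters the 2 lists with opposite sign, this alone favours opposite directions and shows no effect of the extract.

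Genes of retinol metabolism led the authors' deposited table of KEGG maps for TMA against no treatment, with 5 genes (Cyp4a32, Cyp2b9, Cyp4a12b, Ugt2b5 and Cyp3a25), of which 1 was higher and 4 lower, at a false discovery rate of 7.72e-05. That was the only 1 of 62 maps below 0.05 in the authors' deposited table. For EEC+TMA against TMA the first map in the authors' deposited table was arachidonic acid metabolism, with Cyp4a32, Cbr1 and Cyp4a10 higher, at a false discovery rate of 0.0610, and 0 of 60 maps were below 0.05. Monooxygenase activity was among the leading GO terms of the authors' deposited tables, with an adjusted p of 0.00369 in the first comparison (5 genes, 4 of them lower) and 0.00226 in the second (4 genes, all higher). These p-values were made from gene lists on 1 array per group and do not measure the spread between animals.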

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

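The tests of the shuffles after quantile normalization, the poly-A spike-ins, the genomic span in its present form, the intron controls, Xist, the female-biased list and unique probe sets were chosen only after the result was seen. Control probe sets lie outside the comparisons of genes, and some stood higher than on the untreated array beyond level-matched random sets. Poly-A spike-in probe sets differed by 0.99 (log2) on the TMA array, with 38 of 39 higher, and hybridization spike-in probe sets by 0.44, with 16 of 18 higher. Antigenomic background probe sets differed by 0.0587 on the TMA array, with 12 of 23 higher and none lower; among the 11 measured on both arrays all were higher, by a median of 0.82 (1.76-fold), so signal without a target was raised on that array too. Exon normalization controls differed by 0.0231 on the EEC+TMA array, with 693 of 1352 higher and 610 lower. Their random range was 0 wide, so this small difference decides nothing.

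A first pattern is the set of 40 genes, with Ifitm2, Ces2c and Cyp4a32 among them, that were lower on the TMA array than on both others. Sharing the TMA array between the steps gave at most 29 in the central 95% of shuffles, below the 40 observed, but after quantile normalization the margin was narrow (26 against 25). The total of opposite genes lay inside its shuffled range in the deposited scaling (77, range 54.0 to 79) and above it after quantile normalization (84, range 50 to 74.0), but shuffling takes the 3 arrays as equally variable, whereas the TMA array varied most (variance 0.0594 against 0.0449 and 0.0204), so the bound set beforehand could not decide and sharing of a noisier TMA array stays open. After loess removed the trend with level 65.0% of the 40 (26 genes) still passed in both steps. The poly-A spike-ins, higher by 0.99 on the TMA array and lower by a median of -0.99 on the EEC+TMA array against it, are consistent with less mouse RNA relative to spike-in on the TMA array, which may have moved gene values as well. A response to TMA that the extract lessens stays open: with 1 array per group it cannot be told apart from a difference between arrays or animals, nor from the distilled water, which the labels give for the TMA group and not for the untreated one.

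A second pattern is the excess of lower genes on the EEC+TMA array against the untreated one, 176 against 27, with Malat1, Usp34 and Dmxl1 among them. Probe sets that bind several transcripts do not account for it, since with unique probe sets alone 138 were lower and 13 higher. The lower genes spanned a median of 35.6 kb in the files' coordinates. That was above 25.2 kb, the upper bound of the central 95% of level-matched random sets. More unspliced or long RNA on the untreated array could give this. The lower genes of TMA against no treatment spanned 20.2 kb, inside their random range. Yet Malat1, Usp34 and Dmxl1 were already 2.88-fold, 2.11-fold and 1.97-fold lower on the TMA array than on the untreated one. For these genes the lower level was thus not particular to the EEC+TMA array. Spans were first taken from the reference gene table (64.0 kb, against an upper bound of 29.1 kb), which covered 79.5% of the lower genes, too few by the limit set, so the files' own start and stop were used after that result was seen. Intron controls measured on both arrays differed by a median of -0.0702, beyond the bound first set. Yet that bound was 0 wide because so many values are identical, and members went both ways (614 lower, 420 higher). Over all 5331 intron controls, with medians below background, the difference was -0.166 (3152 lower, 1858 higher), again against a range 0 wide. On the TMA array against the untreated one the median difference was -0.0947 over all and 0.064 among those measured on both. The intron controls were taken, after they were seen, as deciding nothing. A response to treatment in long genes stays untested.

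A further pattern is the lower level of male-biased genes with a higher Cyp2b9 on the TMA array. A female liver on that array is argued against by Xist at 1.57, below background, and by all 4 Y-linked genes being measured there, and a trend with level is argued against by the list median of -0.38 after loess, still at percentile 0. A shift towards the female pattern is not settled, since the female-biased list lay at percentile 52.6 with a median of 0. Of its 15 measured members 3 were higher, 7 lower and 5 identical. Under quantile normalization 5 were higher and 10 lower, at percentile 15.1, so Cyp2b9 did not stand for the list. An effect of TMA or of the water given with it, a difference between individual males and the spike-in difference of this array may each contribute and were not separated.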

How the results depend on the processing

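The counts with unique probe sets and without small RNA genes were chosen only after the data were seen. No paired analysis was possible because each group has 1 array and the labels give no replicate numbers, and for the same reason leaving out an array was not possible. No named gene 2-fold apart changed direction, and no list moved to the opposite side of its random range, in the alternatives run: of 1881 gene values under other scalings and probe set rules 1847 kept their side of 2-fold, 30 dropped below it and 4 passed it, and of 966 list medians 890 kept their side of the random range, 18 moved inside and 58 outside. Median centring, not counted here, shifted nothing, as the median difference was already 0, and the second table of values gave the same counts, so neither says anything about stability. The cause of the other shifts was not tested except where the construction shows it.

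At 1.5-fold the counts were 1419 (380 higher) for TMA against no treatment, 1110 (755 higher) for EEC+TMA against TMA and 697 (152 higher) for EEC+TMA against no treatment, with 625 genes opposite in the 2 steps; at 3-fold they were 53 (23 higher), 15 (10) and 52 (4), with 5 opposite. With no background level EEC+TMA against TMA gave 240 genes and the opposite genes numbered 119, since values below background then count. Unique probe sets alone left 202 genes for TMA against no treatment and 105 for EEC+TMA against TMA, and leaving out small RNA genes and antigen receptor segments 183 and 99, from fewer genes. Random lists not matched on level put 17, 23 and 19 lists outside in the 3 comparisons, and quantile normalization left 3 lists outside for EEC+TMA against TMA. Signal over background limits the rest: 928, 853 and 365 genes were measured on 1 array of a pair alone.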

Other observations

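The test of the interferon-gamma list used members written down after its leading genes were seen, without those leading genes. On the EEC+TMA array Cd74 (7.50 against 6.29 on the untreated array), H2-Ab1 (5.64 against 4.33), Gbp10 (8.91 against 7.67), Igtp (7.22 against 6.10) and Cxcl9 (6.07 against 5.05) were higher, all genes that interferon-gamma is known to induce. Among the remaining members, the class I gene H2-K1 was 1.78-fold, the immunoproteasome gene Psmb10 1.76-fold, the peptide transporter gene Tap1 1.45-fold and the transcription factor gene Irf1 1.39-fold higher. Psme2 was 1.31-fold and Iigp1 1.15-fold lower. The class II genes H2-Aa and H2-Eb1 were only 1.12-fold and 1.22-fold higher, and H2-Eb1 was already 1.25-fold higher on the TMA array. H2-DMa and Ciita, both just above background, were identical on the untreated and EEC+TMA arrays. The size of the H2-Ab1 and Cd74 differences was thus not shared by H2-Aa and H2-Eb1.

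A candidate explanation is a raised interferon-gamma type gene group on the EEC+TMA array. Without the leading genes, 13 of 27 measured members were higher, 3 lower and 11 identical. By the bound set beforehand the median of 0, at percentile 49.9, would count against it. That bound could not decide, since with so many identical values the random range of medians ran from 0 to 0. The mean of 0.15 lay at percentile 99.98 (random range -0.12 to 0.07); it was added after the median was seen. Against the TMA array the mean of 0.15 lay inside the random range at percentile 91.5, as did that of TMA against no treatment at 95.6, and the question was left open. Macrophage markers were higher on the same array, and neither observation has a replicate.

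Endothelial markers of liver sinusoids were lower on the TMA array than on both others in the values of some genes, with Kdr 1.89-fold, Stab2 1.70-fold and Cdh5 1.44-fold lower than on the untreated array, and 1.96-fold, 1.89-fold and 1.77-fold higher on the EEC+TMA array than on the TMA array. As a list they stayed inside the random range in both steps, at percentiles 67.9 and 43.0. Trbc2, a T cell receptor constant gene, was 1.72-fold higher on the TMA array than on the untreated array. Its list of T and NK cell markers stayed inside the random range at percentile 87.0. Of 6 measured members 3 were higher and 3 identical, and Cd3e and Cd4 had the same values on both arrays. Hmox1, which encodes the inducible heme oxygenase, was 1.41-fold higher on the TMA array and 1.73-fold higher on the EEC+TMA array, each against the untreated array.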
